A study of Mus musculus with 18 samples.

How the data were processed

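The data were RNA sequencing profiles of mouse cerebral cortex from 18 libraries. The labels placed them in 6 groups of 3, namely libraries labelled Alg13 knockout and libraries labelled wild type at 1, 7 and 30 days after birth. The labels number the replicates of each group but do not say whether they came from separate animals, so p-values measure the spread between these samples, which may be technical. The sex of the animals is not given in the sources used here, and the labels give 1 batch date for all 18 libraries.

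The deposited table held FPKM, that is fragments scaled to transcript length and to the total of mapped fragments, computed by the authors for 28852 genes, with 1 column per library and no pooling of replicates. The submitters' processing notes list Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the mouse genome build GRCm39. The role and order of these tools, the annotation release and any filter are not given in the sources used here. The total FPKM differed between libraries, from 313919 to 394975, so the values were not TPM, which have the same total in every library. The table held no read counts, so absolute depth is not given in the sources used here. Relative depth was estimated from the most frequent ratio of FPKM values under 0.15 to those of wild type day 7 replicate 1. It ranged from 0.90 to 1.21, with a ratio of 1.34 between the deepest and the shallowest library. Because FPKM is relative to the total of a library, a rise of abundant transcripts in a library lowers the FPKM of its other genes.

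For the tests, FPKM was transformed as log2(FPKM + 1), and genes with FPKM of at least 1 in at least 3 of the 18 libraries were kept, which left 13347 genes. Log2 changes are on this scale, which understates the change of genes with low FPKM. The limma package 3.58.1 in R 4.3.3 was fitted to the means of the 6 groups over all 18 libraries with the mean-variance trend, so that the groups shared 1 estimate of the spread. Contrasts compared knockout with wild type at each day, the mean of the 3 daily differences, the genotype by day interaction (moderated F test), and wild type day 7 with day 1 and day 30 with day 7. P-values were adjusted over the 13347 genes by the Benjamini-Hochberg method, with a threshold of 0.05. All adjusted p-values are two-sided and come from limma unless another test is named. Single values of 3 against 3 libraries were compared with exact two-sided permutation tests, for which the smallest possible p is 0.1.

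The 27 gene lists covered protein N-glycosylation, the unfolded protein response, interneurons and inhibitory synapses, other neuronal and glial cell types, neighbouring tissues, blood, sex-specific genes, mitochondrial genes and neighbours of Alg13. They were tested with limma's camera at a preset inter-gene correlation of 0.01, repeated with the correlation estimated from the data, and with limma's fry. P-values were adjusted over the 27 lists within a contrast, and lists with fewer than 5 members past the filter were not tested. Calls within a list were also adjusted over the list alone. The contrasts, the gene lists, the filter and the rule for naming genes were fixed before the data were examined. The file gives the mitochondrially encoded genes other symbols than the list did (COX1, ND1 and so on), and these were matched after the table had been seen. Marker lists for salivary gland, brown fat, liver, lung, skeletal muscle, bone and olfactory bulb were written after a first look at the libraries.

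Genes were named by the following rule. For each knockout comparison these were Alg13 and, among genes with an adjusted p under 0.05, a mean FPKM of at least 1 in the higher group and no overlap between the 3 knockout and 3 wild type libraries (for the mean over days, the same sign on all 3 days), the 10 largest rises and the 10 largest falls. From each list up to 4 members past the threshold were named, or up to 2 with the smallest p where none passed. For the interaction, up to 10 genes past the threshold were named. For the wild type age comparisons, the 5 largest rises and falls with a mean FPKM of at least 10 in the higher group were named. Genes called on 2 or more days were named as well, and gene models without a real name were counted but not named. Some results for genes that the rule selects are not reported here. A gene named outside this rule is described as chosen after its values were seen.

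Gene order along chromosomes was taken from a reference of assembly GRCm38.p6. It is not the build of the table, so it served only to find which genes neighbour each other, and no coordinates are given. Of the 28852 genes 27713 matched it, as did 13299 of the 13347 genes tested. Plac9, Tmem254 and Duxbl1 lie next to each other in a multi-copy region of chromosome 14 and Dynlt1b has near-identical copies, so that fragments of these genes can be divided among copies, and their values are reported as uncertain.

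The replicate numbers were checked as possible pairs from the correlation, across genes, of the deviations of same-numbered knockout and wild type libraries from their group means. At day 7 the correlations were 0.33, 0.34 and 0.53, all above 0.1, so the numbers were treated as paired at that day. The main fit used group means and no pairs. At day 7, as at day 1, wild type replicate 1 correlated best with knockout replicate 2, so the pairing at day 7 is uncertain. At day 1 they were 0.03, 0.13 and 0.10, and at day 30 -0.34, -0.04 and -0.06, so there the numbers were treated as names.

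The alternatives tried were pseudocounts of 0.1 and 0.5, no filter or a filter on mean FPKM, median-of-ratios scaling and quantile normalization, no mean-variance trend, a robust spread, the replicate number as a block, Y-linked expression as a covariate, a minimum log2 change of 1, only the 6 libraries compared, an estimated inter-gene correlation, and leaving out each library in turn. Alternatives chosen after seeing the data were library weights, a replicate block within each day, leaving out the 3 libraries with both Xist and Y-linked transcripts or both replicate 3 libraries of day 7, and 2 treatments of the traces of other tissues. A count test with DESeq2 was intended but was not run, because the table holds no counts.

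The scripts' statistics were tested on simulated data with 13347 genes, of which 100 were changed by a log2 of 1 and 100 by a log2 of 2. Of the genes changed by a log2 of 1, the comparison at day 1 recovered 85%, at day 7 83%, at day 30 84%, the mean over days 95%, the interaction 66%, and the wild type comparisons 84% from day 1 to day 7 and 81% from day 7 to day 30. Of the calls, 4.7%, 6.7%, 5.2%, 1.5%, 4.7%, 3.7% and 10.5% were false in the same order. With the 20 oligodendrocyte and myelin genes shifted by 0.5 at day 7, that list was called and 0 of the 26 other lists were. The simulated noise was independent between genes and had 1 spread per gene for all libraries. These rates therefore do not cover correlated genes or single deviating libraries, both of which matter in the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.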

Results

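RNA sequencing measured gene expression in the cerebral cortex of mice labelled Alg13 knockout or wild type at postnatal days 1, 7 and 30. Each of the 6 groups held 3 libraries. Alg13 is a subunit of the enzyme that adds the second sugar of the lipid-linked precursor of protein N-glycans. The series set out to ask how its loss affects the placement and migration of cortical interneurons. Per library, 11703 to 12780 genes reached 1 FPKM, and 13347 genes entered the tests. Absolute depth is unknown, and the relative depth of the libraries spanned 0.90 to 1.21. The first principal component, with 66.6% of the variance, ordered the libraries by day. The second, with 14.6%, set the day 7 libraries (-31.8 to -26.1) apart on one side and wild type day 1 replicate 3 (57.4) on the other. The remaining libraries lay at 0.989 to 17.7.

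Alg13 (Entrez 67574) itself did not pass the test on any day. At day 1 it measured 2.04 ± 0.862 FPKM in knockout and 2.67 ± 0.676 in wild type (SD, n = 3 each; exact permutation p = 0.4). The log2 difference was -0.30 (SE 0.197, adjusted p = 0.38). At day 7 the means were 2.35 ± 0.423 and 1.80 ± 0.228 FPKM (SD, n = 3 each; exact permutation p = 0.2). At day 30 they were 1.45 ± 0.334 and 1.00 ± 0.191 (SD, n = 3 each; exact permutation p = 0.2). The mean difference over the 3 days was 0.08 (SE 0.114, adjusted p = 0.834). The 18 libraries ranged from 0.83 to 3.27 FPKM, and knockout and wild type values overlapped on all 3 days. The level of Alg13 RNA therefore does not check the genotype labels. A whole-gene FPKM can miss a small deletion, and which part of the gene was altered is not given in the sources used here. The groups are therefore called libraries labelled knockout, and every direction given for them rests on the labels alone.

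**Figure D1:**
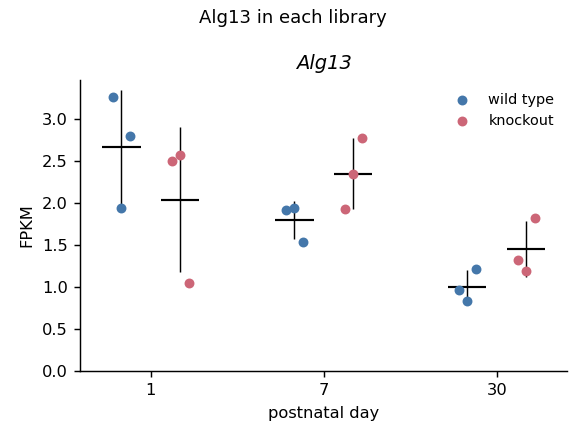
FPKM of Alg13 in each library (vertical axis) by postnatal day (horizontal axis), wild type in blue and libraries labelled knockout in red, with the mean as a horizontal line and the SD as a vertical bar (n = 3). The libraries labelled knockout lie at 1.04 to 2.57 FPKM at day 1, 1.93 to 2.78 at day 7 and 1.19 to 1.82 at day 30, against 1.93 to 3.27, 1.53 to 1.94 and 0.83 to 1.21 in wild type.

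Several libraries held transcripts of other tissues. Wild type day 1 replicate 3 had 9.68% of its total FPKM in salivary gland genes, with Bpifa2 at 14950 FPKM and Smgc at 6308. A further 0.511% lay in brown fat genes, with Fabp4 at 1309 FPKM and Ucp1 at 240. A set of 7 salivary gland genes summed to 38100 FPKM in that library. Their sum was 9.97 to 15.8 FPKM in the other wild type day 1 libraries and all wild type day 7 libraries. Knockout day 1 replicates 2 and 3 lay in the same range, which is 0.026% to 0.042% of the sum in wild type day 1 replicate 3. In the knockout day 7 libraries the sum was at most 1.86 FPKM, so this trace followed the genotype label at day 7. The lung genes, led by Scgb1a1, made up to 0.0318% of total FPKM (wild type day 1 replicate 1). Scgb1a1 was at 0.182 and 0.139 FPKM in replicate 2 of wild type and of knockout at day 30 against 16.8 to 79.7 in the other libraries. Other shares peaked at 0.0352% for liver (wild type day 30 replicate 3) and 0.0191% for skeletal muscle (wild type day 1 replicate 3). The highest were 0.00679% for bone (knockout day 30 replicate 3) and 0.00724% for olfactory bulb (knockout day 1 replicate 3). Xist, the RNA of the inactive X chromosome of females, occurred together with Y-linked transcripts in wild type day 1 replicate 3 (39.5 FPKM), knockout day 1 replicate 3 (23.8 FPKM) and wild type day 30 replicate 2 (31.5 FPKM). Wild type day 1 replicate 2 had Xist at 157 FPKM and Ddx3y at 0.031. Every library besides these had Ddx3y at 11.7 FPKM or more and Xist at 0.065 or less. Among them, wild type day 1 replicate 1 had Ddx3y at 20.5 FPKM and Xist at 0.065. These values argue against technical repeats of 1 animal for wild type day 1 replicates 1 and 2, and do not cover the other libraries. Within groups the libraries correlated, across genes, at r of 0.893 to 0.979 in wild type day 1 and at 0.974 or more elsewhere.

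**Figure D2:**
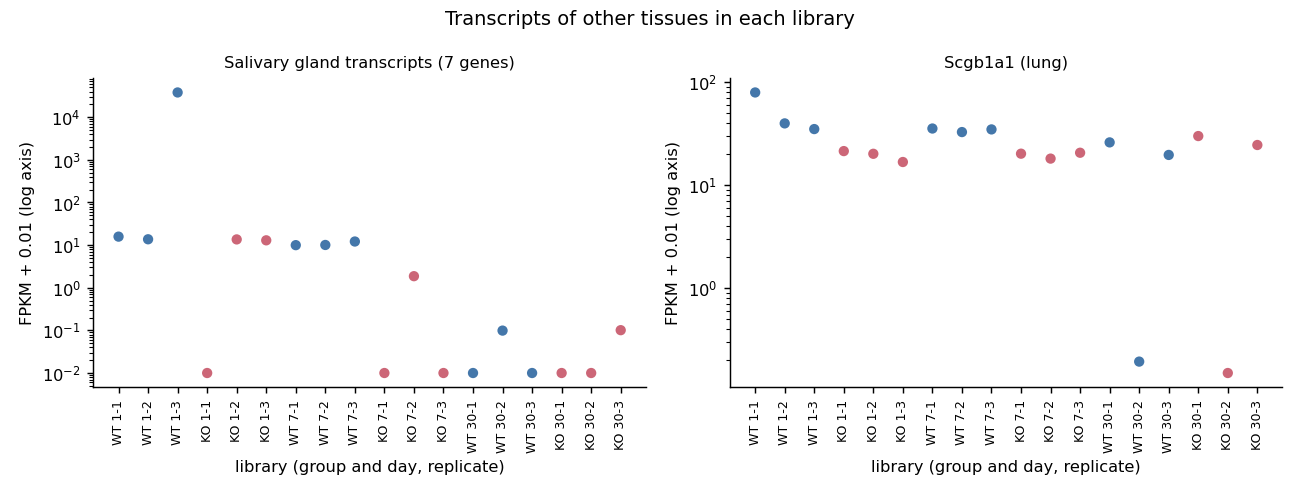
Sum of 7 salivary gland genes (left) and Scgb1a1, a lung gene (right), in FPKM plus 0.01 on a logarithmic vertical axis, for each library by postnatal day, wild type in blue and libraries labelled knockout in red. Wild type day 1 replicate 3 reached 38100 FPKM for the salivary sum, and wild type day 7 lay at 9.97 to 12.1 FPKM against 0 to 1.86 in libraries labelled knockout.

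The comparison at day 1 asked how knockout and wild type cortex differ just after birth. Of 13347 genes, 69 passed the threshold, 48 higher and 21 lower in libraries labelled knockout. No overlap between groups was found for all 69, and for 1974 genes (14.8%) in all against 10% by chance. Neuronal and glial genes were among the largest rises. Calb1, the calcium buffer calbindin, measured 8.16 ± 4.46 FPKM against 2.13 ± 0.917 in wild type (SD, n = 3 each; log2 1.49, SE 0.272, adjusted p = 0.0256). Slc17a7, the vesicular glutamate transporter VGLUT1, measured 32.3 ± 14.6 against 12.6 ± 3.26 (log2 1.23, SE 0.222, adjusted p = 0.024). Ndn (Entrez 17984), a paternally expressed imprinted gene of neurons, rose from 82.8 ± 8.92 to 183 ± 55.7 FPKM (log2 1.10, SE 0.193, adjusted p = 0.0204). The neuronal RNA-binding protein gene Elavl4 rose by 0.93 (SE 0.133, adjusted p = 0.00782). Aqp4, the astrocyte water channel gene, rose by 0.95 (SE 0.152, adjusted p = 0.0124) and the oligodendrocyte lineage factor gene Olig1 by 0.73 (SE 0.119, adjusted p = 0.0126). Dynlt1b (Entrez 21648) and Dynll1, both encoding dynein light chains, rose by 1.27 and 0.94, and Rprml, Acsbg1 and Cerox1 by 1.29, 0.96 and 0.85. Among the falls, Tmem254 (Entrez 66039) measured 7.47 ± 1.59 FPKM against 21.2 ± 7.28 (log2 -1.35, SE 0.185, adjusted p = 0.00771). Its neighbours Duxbl1 (Entrez 278672) and Plac9 (Entrez 211623) changed by -1.35 and -2.24. Fbn1, the gene of the matrix protein fibrillin-1, fell from 8.06 ± 3.59 to 2.72 ± 0.388 FPKM (log2 -1.22, SE 0.193, adjusted p = 0.0124). Adamts2, a procollagen protease gene, fell by 0.93. The clock gene Per2 fell by 0.90, and Spon2, Mvp, Mid1 and Kremen1 by 1.26, 1.20, 0.96 and 0.81. A fit of only the 6 day 1 libraries called 0 genes (limma; 767 at an unadjusted p under 0.05). The count moved with single libraries, to 10 genes (8 higher and 2 lower) without knockout day 1 replicate 3, and 26 (20 and 6) without knockout day 1 replicate 2. It was 224 (109 and 115) without wild type day 1 replicate 3 and 1531 (897 and 634) without wild type day 1 replicate 2. The latter is the library with Xist at 157 FPKM and Ddx3y at 0.031, so sex-linked transcripts were not balanced between the labels at day 1. With Y-linked expression as a covariate, 736 genes were higher and 409 lower. The cause of these larger counts was not tested. Of 21 named genes, 17 lost their call without knockout day 1 replicate 3, and Dynlt1b, Elavl4, Tmem254 and Duxbl1 did not. All 69 genes kept more than 0.5 of their log2 change without it (median 0.918). Calls were lost by 10 of the 21 without knockout day 1 replicate 2, 6 without wild type day 1 replicate 1, 5 without knockout day 1 replicate 1 and 1 without wild type day 1 replicate 3. Quantile normalization gave 40 higher and 9 lower.

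The interneuron genes, the subject of the series, lay higher in libraries labelled knockout at day 1 as lists but seldom singly. All 20 pan-GABAergic interneuron genes had positive differences (median log2 0.40, camera adjusted p = 0.00459; adjusted p = 0.904 with an estimated correlation). Of these, 0 passed over all genes tested and 0 adjusted over the list alone. Gad1, which makes GABA, measured 18 ± 7.05 against 9.75 ± 5.17 FPKM (SD, n = 3 each; adjusted p = 0.137). Of 23 interneuron subtype genes Calb1 alone rose, 2 adjusted over the list alone (median 0.19, adjusted p = 0.0352; adjusted p = 0.904 with an estimated correlation). Of 23 GABA receptor and inhibitory synapse genes 22 had positive differences (median 0.36, adjusted p = 0.000321; adjusted p = 0.904 with an estimated correlation). Over all genes 0 of them passed, and 3 did adjusted over the list alone. Gabra4 differed by 0.63 and Gabrg1 by 0.55, with adjusted p of 0.0802 and 0.0639. Wild type day 1 replicate 3, the library with other-tissue RNA, had the lowest Gad1 (4.73 FPKM) and Sst (17.4 FPKM) of the 6. Without it the medians were 0.154 (adjusted p = 0.465), 0.161 (adjusted p = 0.465) and 0.162 (adjusted p = 0.294) for the pan-GABAergic, subtype and receptor lists. Knockout day 1 replicate 3 had the highest day 1 values of Gad1 (26.2 FPKM) and Sst (147 FPKM). The subtype list without it had a median of 0.175 (adjusted p = 0.0826). The 28 genes of neuronal migration and guidance had a median of 0.02 (adjusted p = 0.947), and 0 passed.

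**Figure D3:**
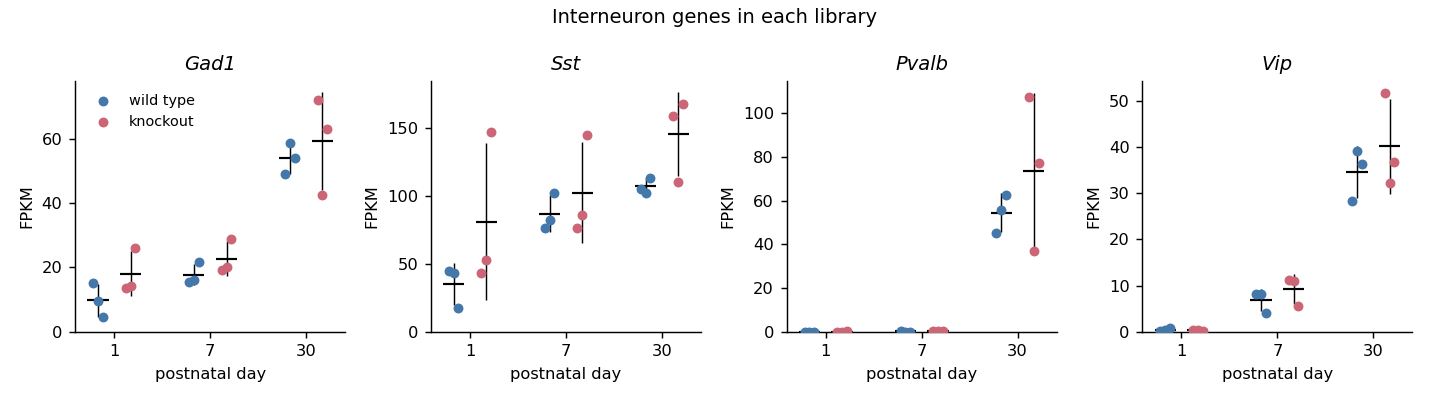
FPKM of the interneuron genes Gad1, Sst, Pvalb and Vip in each library by postnatal day, wild type in blue and libraries labelled knockout in red, with the mean as a horizontal line and the SD as a vertical bar (n = 3). Knockout day 1 replicate 3 is the highest day 1 library for Gad1 (26.2 FPKM) and Sst (147 FPKM), and Pvalb rose in wild type from 0.136 FPKM at day 7 to 54.5 at day 30.

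Other cell types at day 1 split by lineage. Of 15 astrocyte genes 11 had positive differences (median 0.40, adjusted p = 0.00538; adjusted p = 0.904 with an estimated correlation). Aqp4 rose, 4 genes did adjusted over the list alone, and the list call ended without wild type day 1 replicate 2 (adjusted p = 0.0921). Endothelial and pericyte genes were negative in 13 of 15 (median -0.33, adjusted p = 0.0249; adjusted p = 0.904 with an estimated correlation). So were 11 of 14 meninges and fibroblast genes (median -0.80, adjusted p = 0.0418; adjusted p = 0.904 with an estimated correlation). Over all genes 0 members were called in either list, and 0 and 1 adjusted over the list alone. For example, Cdh5 differed by -0.88 (adjusted p = 0.137), and Pecam1 by -0.86 (adjusted p = 0.139). Mgp measured 5.98 ± 2.16 against 12.8 ± 3.39 FPKM (adjusted p = 0.0894), while Ptgds of the meninges list differed by 0.76. Wild type day 1 replicate 3, with its other-tissue RNA, had Cdh5 at 23.5 FPKM against 6.25 and 8.51 in the other wild type libraries. Without it the endothelial median was 0.003 (adjusted p = 0.465) and the meninges median -0.078 (adjusted p = 0.465). The endothelial call also ended without knockout day 1 replicate 3 (median -0.106, adjusted p = 0.113). The meninges call ended without wild type day 1 replicate 2 (adjusted p = 0.0921) and knockout day 1 replicate 1 (adjusted p = 0.206). No other list passed at day 1. Of the glycosylation lists, the 22 genes of lipid-linked oligosaccharide assembly had a median of 0.01 (adjusted p = 0.942). The 23 genes of oligosaccharide transfer and glycan processing had a median of -0.05 (adjusted p = 0.815). The unfolded protein response had a median of -0.05 (adjusted p = 0.22), with Sesn2 at -1.36 (adjusted p = 0.0514). Medians of the other lists were 0.07 for excitatory neurons, 0.16 for glutamate receptors, 0.12 for sodium, potassium and HCN channels, 0.01 for oligodendrocytes and myelin, 0.30 for oligodendrocyte precursors, and -0.19 for microglia. They were -0.08 for choroid plexus, -0.83 for blood, 0.18 for striatum, -0.12 for hippocampus, -0.05 for thalamus, septum and hypothalamus, 0.17 for perineuronal nets, -0.06 for mitochondrial genes and 0.17 for the neighbours of Alg13 (adjusted p from 0.0739 to 0.942). In the progenitor list the median of -0.11 and the mean of 0.03 differed in sign (adjusted p = 0.835). So they did in the immediate-early (-0.02 and 0.04) and sex-specific (0.48 and -0.14) lists (adjusted p of 0.945 and 0.902). In these lists Olig1 and Slc17a7 alone passed over all genes. Adjusted over the list alone, those that passed included 3 myelin, 3 perineuronal net, 2 precursor, 2 blood, 1 excitatory and 1 immediate-early gene upward and 1 unfolded protein response gene downward.

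The comparison at day 7 asked the same question at the end of the first postnatal week. Tmem254 alone passed, at 13.6 ± 0.538 FPKM in libraries labelled knockout against 39.2 ± 1.86 in wild type (SD, n = 3 each; log2 -1.47, SE 0.185, adjusted p = 0.0079). The call of Tmem254 at day 7 ended on leaving out wild type day 7 replicate 1, 2 or 3 (adjusted p of 0.0686, 0.0919 and 0.054). It also ended without knockout day 7 replicate 1 or 3 (0.0852 and 0.0547). Without each of these in turn 0 genes passed (limma; 232 to 598 at an unadjusted p under 0.05), and 2 passed without knockout day 7 replicate 2. A fit of only the 6 day 7 libraries called 9 genes. At an unadjusted p under 0.05 there were 470 genes, and 2749 (20.6%) had no overlap between the groups against 10% by chance.

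Myelin genes formed the clearest group at day 7. All 20 oligodendrocyte and myelin genes had positive differences (median log2 0.35, camera adjusted p = 2.56e-14; fry adjusted p = 0.0633). It was the only knockout list call that held with an estimated correlation (adjusted p = 0.0475). The median was 0.211 without wild type day 7 replicate 1 (adjusted p = 4.71e-10). No member passed over all genes, but 5 did adjusted over the list alone, among them Mbp and Mag. Mbp, myelin basic protein, measured 17.6 ± 3.25 against 9.20 ± 3.28 FPKM (SD, n = 3 each; adjusted p = 0.384 over all genes). Mag, myelin-associated glycoprotein, measured 2.94 ± 0.692 against 1.11 ± 0.845 (adjusted p = 0.471 over all genes). Positive differences were also found in 14 of 15 microglia genes (median 0.42, adjusted p = 5.33e-10; adjusted p = 0.133 with an estimated correlation). Of these, 2 passed adjusted over the list alone and 0 over all genes, and P2ry12 differed by 0.75. Of the interneuron lists, the subtype genes had a median of 0.21 with 20 of 23 positive (adjusted p = 2.68e-05; adjusted p = 0.133 with an estimated correlation). The GABA receptor genes had a median of 0.20 with 19 of 23 positive (adjusted p = 1.1e-05; adjusted p = 0.242 with an estimated correlation). In both lists 0 members passed in either way, and Calb1 differed by 0.80. The pan-GABAergic list, by contrast, was not called, with a median of 0.02, 10 of 20 positive and an adjusted p of 0.444. Its change from the day 1 difference was -0.40 (adjusted p = 0.0802).

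Another 8 lists were called upward at day 7 with 0 members passing over all genes or adjusted over the list alone. Their medians and adjusted p, followed by the adjusted p with an estimated correlation, were 0.22, 1.9e-05 and 0.366 for the ion channels; 0.18, 0.000447 and 0.133 for immediate-early genes; 0.12, 0.000835 and 0.526 for glutamate receptors; and 0.33, 0.00143 and 0.133 for 5 hippocampus genes. They were 0.14, 0.00639 and 0.262 for astrocytes; 0.20, 0.00789 and 0.638 for mitochondrial genes; 0.05, 0.0231 and 0.526 for oligodendrocyte precursors; and 0.27, 0.0262 and 0.133 for 5 choroid plexus genes. Knockout day 7 replicate 3 had Ttr, a choroid plexus transcript, at 137 FPKM. Without it the choroid plexus median was -0.071 (adjusted p = 0.627), the precursor median -0.014 (adjusted p = 0.205) and the hippocampus adjusted p 0.113. Wild type day 7 replicate 3 had the olfactory bulb gene Cdhr1 at 15.5 FPKM. Without it the calls of the channel (adjusted p = 0.229), glutamate (adjusted p = 0.113), precursor (adjusted p = 0.0573), astrocyte (adjusted p = 0.249) and choroid plexus (adjusted p = 0.0688) lists ended. The mitochondrial call ended without wild type day 7 replicate 1 (adjusted p = 0.0787). The other 15 lists had adjusted p of 0.248 or more, including lipid-linked oligosaccharide assembly (median 0.01), oligosaccharide transfer (0.03), the unfolded protein response (0.07) and migration (-0.01). In the migration list Slit2 differed by 0.46 and was the 1 gene to pass adjusted over the list alone. The mean and test of that list were positive, and the endothelial and perineuronal net lists had positive medians and negative means.

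The comparison at day 30 addressed the juvenile cortex, and 3 genes passed. Dynlt1b rose to 7.70 ± 1.84 FPKM in libraries labelled knockout from 3.01 ± 0.666 in wild type (SD, n = 3 each; log2 1.11, SE 0.159, adjusted p = 0.02). Tmem254 fell from 19.8 ± 1.11 to 7.93 ± 0.838 FPKM (log2 -1.22, SE 0.185, adjusted p = 0.0251). Rskr fell from 6.69 ± 1.09 to 3.29 ± 0.504 (log2 -0.84, SE 0.114, adjusted p = 0.02). At an unadjusted p under 0.05 there were 479 genes, and 1983 (14.9%) had no overlap between the groups against 10% by chance. Without wild type day 30 replicate 2, knockout day 30 replicate 2 or knockout day 30 replicate 3 the count was 0 (limma; 284, 943 and 281 at an unadjusted p under 0.05). It was 1, Dynlt1b, without wild type day 30 replicate 3 and 16 (1 higher and 15 lower) without wild type day 30 replicate 1. Tmem254 at day 30 had an adjusted p of 0.108 without knockout day 30 replicate 1. Among the 4 day 30 libraries with the lung trace, Tmem254 differed by -1.33 (adjusted p = 0.391), Dynlt1b by 0.90 (adjusted p = 0.399) and the median of the myelin list was 0.304. Quantile normalization gave 2 higher and 2 lower, and no filter 3 and 25, against 1 and 2.

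Myelin genes again lay higher at day 30, with all 20 positive (median log2 0.29, camera adjusted p = 1.2e-10; fry adjusted p = 0.111; adjusted p = 0.131 with an estimated correlation). Over all genes or adjusted over the list alone, 0 passed. Ugt8a and Fa2h, both enzymes of myelin lipid synthesis, differed by 0.54 and 0.43. The myelin difference was 0.25 larger than at day 1 both at day 7 (adjusted p = 0.0532) and at day 30 (adjusted p = 0.0557), so a change with age was not established. Astrocyte genes went the other way, with 14 of 15 negative (median -0.15, adjusted p = 0.00599; adjusted p = 0.428 with an estimated correlation). This differed from day 1 by -0.545 (adjusted p = 1.28e-05; adjusted p = 0.219 with an estimated correlation). All 10 blood genes were positive (median 0.61, adjusted p = 4.8e-06; adjusted p = 0.428 with an estimated correlation), led by S100a8 at 2.03, with 0 passing. Knockout day 30 replicate 3 held S100a8 at 22.5 FPKM and Hbb-bs at 1262. Without it the median was 0.123 (adjusted p = 0.132). Oligodendrocyte precursors (median 0.20, adjusted p = 0.0479), progenitors (0.11, adjusted p = 0.0479) and ion channels (-0.10, adjusted p = 0.0498) were called near the threshold, with 0 members passing. With an estimated correlation these had adjusted p of 0.877, 0.904 and 0.925. Each of these calls ended without wild type day 30 replicate 2 (adjusted p of 0.221, 0.189 and 0.189) and without knockout day 30 replicate 2 (0.984, 0.164 and 0.16). The precursor call also ended without wild type day 30 replicate 3 (0.116) and the progenitor call without knockout day 30 replicate 3 (0.187). The channel call ended without wild type day 30 replicate 1 (0.0725) or knockout day 30 replicate 1 (0.266). The remaining 21 lists had adjusted p of 0.061 or more, among them the pan-GABAergic (median 0.11, adjusted p = 0.345) and interneuron subtype (0.17, adjusted p = 0.116) lists. The pan-GABAergic difference had moved by -0.295 from day 1 (adjusted p = 0.0288; adjusted p = 0.792 with an estimated correlation). Also among them were the oligosaccharide assembly (0.05, adjusted p = 0.132), oligosaccharide transfer (0.13, adjusted p = 0.119) and unfolded protein response (0.12, adjusted p = 0.162) lists. In the GABA receptor, excitatory neuron, striatum and immediate-early lists the test was downward with a positive median, and the sex-specific list had a mean of -0.10 and a median of 0.26.

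**Figure D4:**
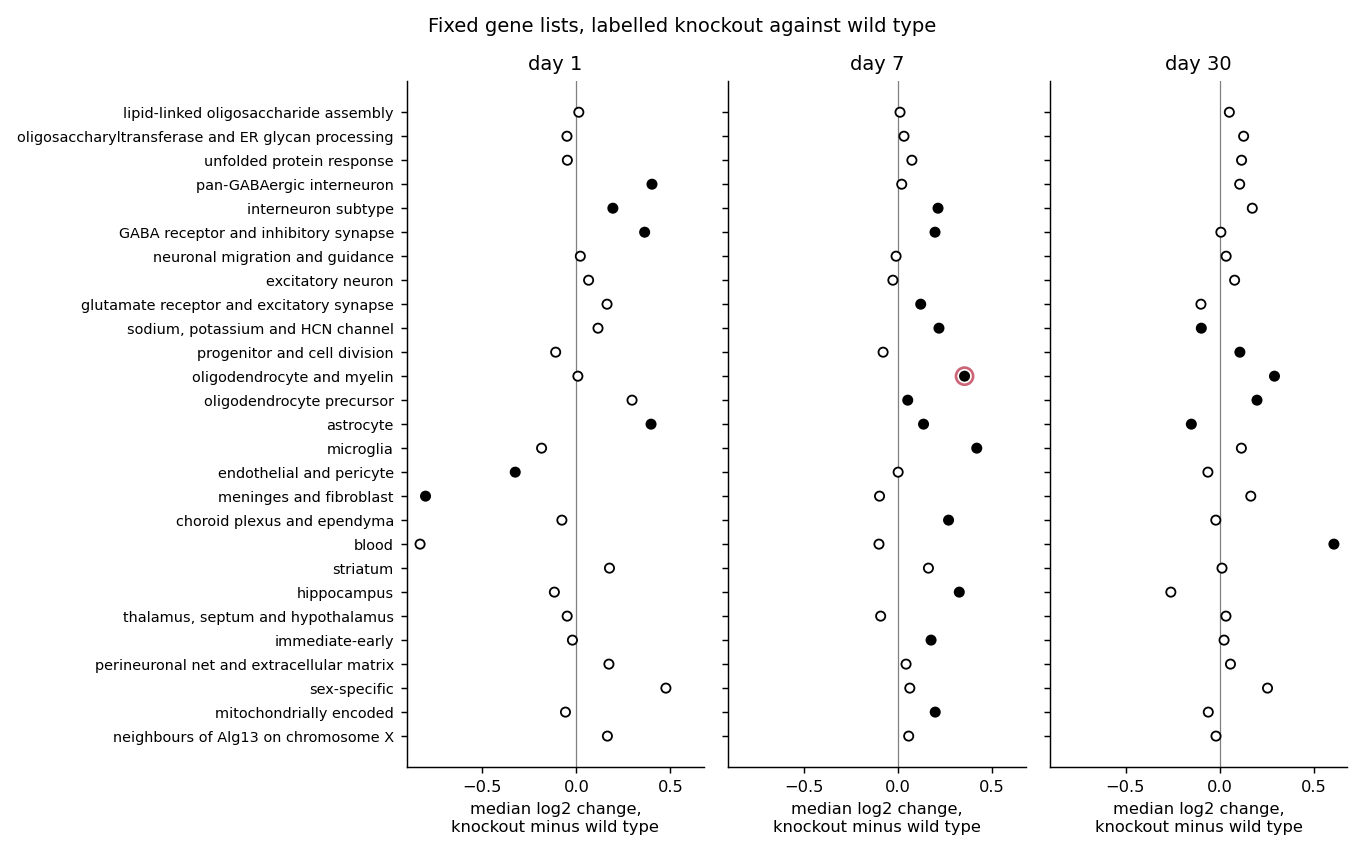
Median log2 difference, knockout minus wild type labels, of each of 27 gene lists (vertical axis) at days 1, 7 and 30 (panels from left to right), with filled points for lists with a camera adjusted p under 0.05 and a red ring for the list also called with an estimated correlation. The oligodendrocyte and myelin list lies at 0.01, 0.35 and 0.29, with the ring at day 7, and the pan-GABAergic list at 0.40, 0.02 and 0.11.

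Averaging the 3 daily differences asked which genes differed in the mean over days. In this test 13 genes passed, 9 higher and 4 lower in libraries labelled knockout. A gene can pass it without a difference on every day. Septin8, one of the 13, lay at 62.2 to 62.9 FPKM in wild type at day 30. In libraries labelled knockout it lay at 62.4 to 64.8 FPKM at that day. Tmem254 had the smallest adjusted p, with a mean log2 difference of -1.35 (SE 0.107, adjusted p = 1.19e-05). The neighbouring Plac9 and Duxbl1 changed by -2.03 (SE 0.219, adjusted p = 0.000291) and -0.69 (SE 0.099, adjusted p = 0.00704). Dynlt1b rose by 1.04 (SE 0.092, adjusted p = 2.72e-05). These 4 genes lie in multi-copy regions or have near-identical copies, so their FPKM is uncertain. Ndn rose by 1.00 (SE 0.111, adjusted p = 0.00031). Its means were 82.8, 93.0 and 26.6 FPKM in wild type and 183, 162 and 59.3 in libraries labelled knockout at days 1, 7 and 30. Zkscan3 (Entrez 72739), which encodes a zinc-finger protein, rose by 0.64 (SE 0.07, adjusted p = 0.000291). Other rises were those of Nrn1, the neuritin gene (0.78, adjusted p = 0.0338), Brinp3 (0.47, adjusted p = 0.0187) and Olfm3 (0.41, adjusted p = 0.0198). The ETS factor gene Elk1 (0.41, adjusted p = 0.0454), Scoc (0.34, adjusted p = 0.0311) and Septin8 (0.29, adjusted p = 0.0483) rose as well. Maml1, a coactivator of Notch, fell by 0.37 (adjusted p = 0.048). For Dynlt1b, Tmem254, Ndn and Plac9 the test of a difference between days gave adjusted p of 0.575, 0.867, 0.731 and 0.825. Tmem254, Plac9, Dynlt1b, Ndn, Zkscan3 and Duxbl1 were called on leaving out any 1 library. Without knockout day 7 replicate 2 or 3 or knockout day 30 replicate 1 or 3 only these 6 of the 13 were called, 3 higher and 3 lower. The number was 7 without wild type day 30 replicate 2, and 8 without wild type day 7 replicate 1 or 2, knockout day 7 replicate 1 or wild type day 30 replicate 1 or 3. The total count was 57 (43 higher and 14 lower) without wild type day 1 replicate 2 and 15 (5 and 10) without wild type day 30 replicate 1.

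**Figure D5:**
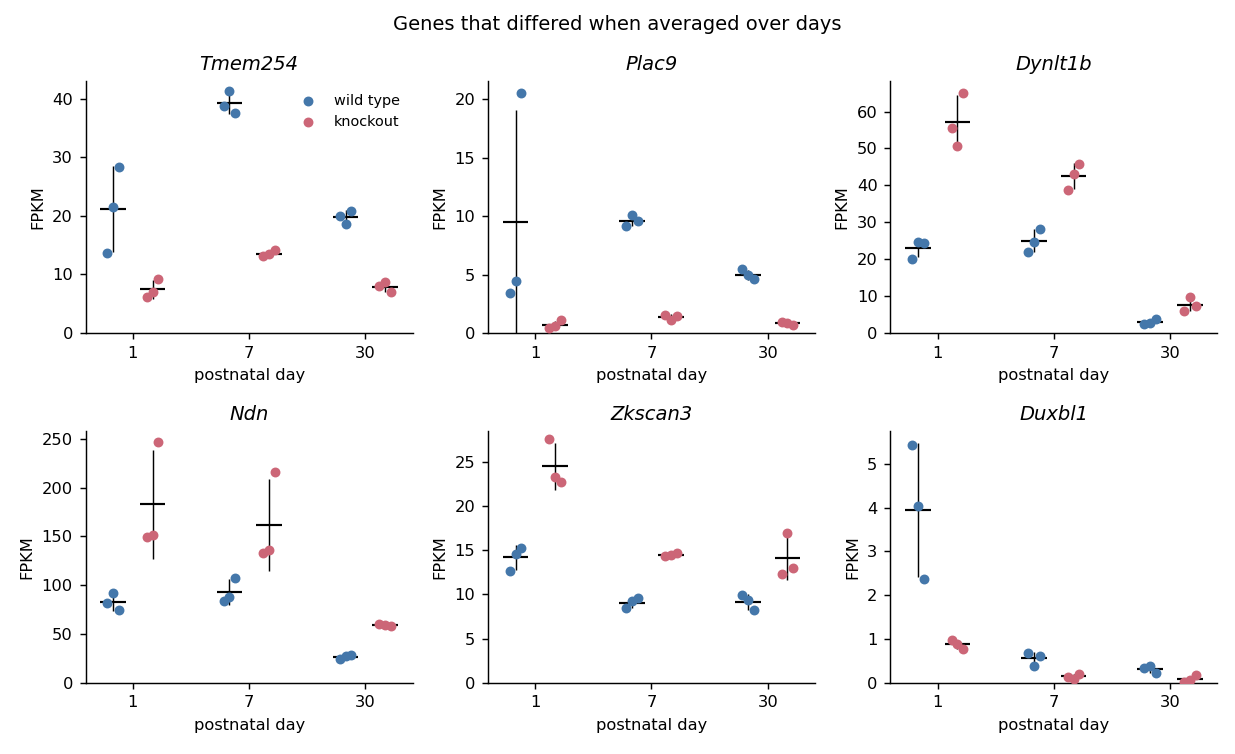
FPKM of Tmem254, Plac9, Dynlt1b, Ndn, Zkscan3 and Duxbl1 in each library by postnatal day, wild type in blue and libraries labelled knockout in red, with the mean as a horizontal line and the SD as a vertical bar (n = 3). Tmem254 lies at 7.47, 13.6 and 7.93 FPKM in libraries labelled knockout against 21.2, 39.2 and 19.8 in wild type at days 1, 7 and 30, and Ndn at 183, 162 and 59.3 against 82.8, 93.0 and 26.6.

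Over the 3 days 8 of 27 lists were called, and 0 held with an estimated correlation. In the myelin list 19 of 20 genes were positive, and 12 passed adjusted over the list alone but 0 over all genes. Its median was 0.32 (camera adjusted p = 9e-12; fry adjusted p = 0.00631; adjusted p = 0.0941 with an estimated correlation). GABA receptor genes were positive in 22 of 23 (median 0.19, adjusted p = 8.63e-06; adjusted p = 0.429 with an estimated correlation). Subtype genes were positive in 22 of 23 (median 0.18, adjusted p = 1.74e-05; adjusted p = 0.329 with an estimated correlation) and pan-GABAergic genes in 19 of 20 (median 0.15, adjusted p = 0.00164; adjusted p = 0.679 with an estimated correlation). Adjusted over the list alone, 1, 3 and 0 members of these lists passed, and over all genes 0. Oligodendrocyte precursors had a median of 0.19 (adjusted p = 0.000678; adjusted p = 0.429 with an estimated correlation) and microglia 0.19 (adjusted p = 0.0147; adjusted p = 0.832 with an estimated correlation). Astrocytes had a median of 0.14 (adjusted p = 0.0256; adjusted p = 0.644 with an estimated correlation) and endothelium and pericytes -0.13 (adjusted p = 0.0256; adjusted p = 0.832 with an estimated correlation). Of these 4 lists 1, 1, 0 and 0 members passed adjusted over the list alone. The pan-GABAergic call ended without wild type day 1 replicate 3 (median 0.063, adjusted p = 0.124). The endothelial call ended without wild type day 1 replicate 3, knockout day 1 replicate 3 or knockout day 7 replicate 3 (adjusted p of 0.295, 0.113 and 0.0589). The microglia and astrocyte calls both ended without wild type day 1 replicate 2 (0.178 for both), knockout day 1 replicate 3 (0.113 for both), wild type day 7 replicate 3 (0.16 for both), knockout day 7 replicate 2 (0.0568 and 0.0557) or wild type day 30 replicate 2 (0.0505 for both). The astrocyte call also ended without wild type day 1 replicate 3 (0.0691) or knockout day 30 replicate 2 (0.0606). The other 19 lists had adjusted p of 0.0821 or more, with 1 gene each of the migration, excitatory and blood lists passing adjusted over the list alone. The blood median was -0.03 with a mean of 0.08, and the sex-specific median 0.28 with a mean of -0.06.

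The interaction of genotype label and day asked which differences changed with age, and 2 genes passed. Hpcal4, a neuronal calcium sensor gene, differed by 0.77, 0.56 and -0.44 at days 1, 7 and 30 (SE 0.124, adjusted p = 0.0461). Its FPKM in the same order was 13.8 against 7.60, 67.9 against 45.6 and 185 against 251. Ldoc1 differed by 0.72, -0.51 and 0.12 (SE 0.114, adjusted p = 0.0461). At an unadjusted p under 0.05 there were 1225 genes. The count was 4 without wild type day 1 replicate 2, 2 without wild type day 1 replicate 1 and 1 without knockout day 7 replicate 2, and the last 2 settings called neither Hpcal4 nor Ldoc1. It was 0 without knockout day 1 replicate 2 or 3, without any other day 7 library and without any day 30 library (limma; 779 to 1423 at an unadjusted p under 0.05). With the replicate number as a block the count was 0 as well. Across genes, which are not independent replicates, the day 1 differences correlated with those at day 7 at r = 0.056 and with those at day 30 at r = 0.173. Those at days 7 and 30 correlated at r = -0.116.

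Wild type cortex was compared between days as a measure of normal development. From day 1 to day 7, 2787 genes rose and 3741 fell. The balance depended on the setting, with 3156 up and 3118 down under median-of-ratios scaling and 946 up and 591 down at a log2 change of at least 1. The largest rises were Gpr37l1, from 0.538 ± 0.11 to 27.5 ± 6.69 FPKM (SD, n = 3 each; log2 4.19, SE 0.187, adjusted p = 8.81e-10), and the synaptic kinase gene Camk2a (9.83 ± 5.51 to 170 ± 53.3 FPKM). Aqp4 (1.85 ± 0.644 to 44.7 ± 2.02 FPKM), Slc30a3 and Ddn followed. The largest falls were Igfbpl1, from 60.8 ± 15.6 to 2.16 ± 3.23 FPKM (log2 -4.74, SE 0.528, adjusted p = 3.7e-06), and Xist, whose day 1 libraries differed in sex-linked transcripts. Sox11 and Sox4, transcription factors of immature neurons, changed by -2.93 and -2.70, and Gpc2 by -2.86. Of 15 astrocyte genes 13 rose and 1 fell (median 1.59, adjusted p = 3.35e-09), the only list at this step to hold with an estimated correlation (adjusted p = 0.0489). The GABA receptor list had a median of 1.11 with 18 of 23 up and 1 down (adjusted p = 3.35e-09; adjusted p = 0.272 with an estimated correlation). It included the chloride transporter gene Slc12a5 at 2.47. Ion channels (17 of 20 up), glutamate receptors (18 of 21), microglia (12 of 15), oligodendrocyte precursors (9 of 10) and myelin (10 of 20) were called upward and progenitors (17 of 20 down, median -0.85) downward. These had adjusted p of 0.0011 or less, and of 0.336 to 0.363 with an estimated correlation. Interneuron subtype genes rose in 13 of 23 and fell in 3 (median 0.85, adjusted p = 0.00607; adjusted p = 0.363 with an estimated correlation). That call ended without wild type day 1 replicate 3 (adjusted p = 0.111). Pan-GABAergic genes divided (median -0.17, adjusted p = 0.732), with the vesicular GABA transporter gene Slc32a1 up by 1.16 and the transcription factor genes Dlx2 and Dlx5 down, at -1.43 and -1.07. Mitochondrial genes were called at an adjusted p of 0.0498 (0.832 with an estimated correlation). This was lost without wild type day 1 replicate 1 or 2 (0.102 and 0.324) or wild type day 7 replicate 2 or 3 (0.0975 and 0.0822). The excitatory list had a median of -0.52 and a mean of 0.07, and the sex-specific list 0.34 and -0.29. The meninges, choroid plexus and blood lists had an upward test with medians of -0.19, -0.40 and -0.26.

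From day 7 to day 30, 2777 genes rose and 3956 fell in wild type, against 3378 and 3252 under median-of-ratios scaling and 944 and 988 at a log2 change of at least 1. Pvalb, the parvalbumin of fast-spiking interneurons, rose from 0.136 ± 0.0657 to 54.5 ± 8.91 FPKM (SD, n = 3 each; log2 5.60, SE 0.259, adjusted p = 2.3e-10). The myelin genes Mal and Mobp rose by 4.85 and 4.82 and Fam107a by 5.12. The largest falls were those of Dpysl3, Cd24a, Dpysl5, Trim67 and Tubb2b. Dpysl3 went from 500 ± 94.4 to 6.73 ± 0.317 FPKM (log2 -6.00, SE 0.2, adjusted p = 1.66e-11). Dpysl5 and Tubb2b followed at -5.72 and -4.47, and Cd24a and Trim67 at -5.73 and -4.48. Of 20 myelin genes 17 rose and 0 fell (median 2.32, adjusted p = 2.11e-14), which held with an estimated correlation (adjusted p = 0.0465). Interneuron subtype genes rose in 13 of 23 and fell in 2 (median 0.82, adjusted p = 0.000237; adjusted p = 0.235 with an estimated correlation). Among them were Lamp5, Calb1 and Vip at 4.62, 2.40 and 2.23. Microglia (14 of 15 up), astrocytes (12 of 15), mitochondrial genes (13 of 13), ion channels (11 of 20), immediate-early genes (9 of 15), endothelium (7 of 15) and hippocampus (2 of 5) were called upward and progenitors (14 of 20 down) downward. These had adjusted p of 0.0236 or less, and of 0.135 to 0.408 with an estimated correlation. In the wild type libraries the mitochondrial genes took 11.3% to 12.1% of total FPKM at day 7 and 22.9% to 26.3% at day 30. Pan-GABAergic genes again divided, with Gad1 up by 1.56 and Lhx6 and Dlx1 down, at -1.36 and -1.26. Of 28 migration genes 3 rose and 13 fell, with Dcx, doublecortin, at -3.99 (list adjusted p = 0.0628). The unfolded protein response, precursor and choroid plexus lists had an upward test with medians of -0.10, -0.23 and -0.11.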

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

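The results here are changes between days in the difference between the labels, each from a test of the difference itself. The splits of the libraries were planned. The relabelling within pairs and the tests on neighbouring genes, on carried-over transcripts, on single libraries at day 1, on the position along development and on the astrocyte list were chosen only after the results had been seen.

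The difference between the labels changed across days for Hpcal4 and Ldoc1 (limma F test, adjusted p = 0.0461 for both). Of the gene lists, the microglia difference was 0.496 higher at day 7 than at day 1 in median log2. From day 1 to day 30 the list difference moved by 0.157 for the unfolded protein response, -0.295 for pan-GABAergic interneurons, -0.394 for GABA receptors, -0.196 for glutamate receptors, -0.545 for astrocytes, 0.968 for meninges and fibroblasts and 1.51 for blood. From day 7 to day 30 it moved by -0.164 for GABA receptors, -0.208 for glutamate receptors, -0.326 for ion channels, 0.226 for progenitors, -0.321 for astrocytes, -0.258 for microglia, 0.689 for blood, -0.627 for hippocampus, -0.234 for immediate-early genes and -0.187 for mitochondrial genes. Camera called each of these at the preset correlation, and none held with an estimated correlation (adjusted p from 0.154 to 0.933). The day 1 libraries in these differences include wild type day 1 replicate 3, with 9.68% of its FPKM in salivary gland genes, and the day 30 libraries include knockout day 30 replicate 3, with S100a8 at 22.5 FPKM.

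The first pattern was the set of 13 genes of the mean over days, Tmem254, Plac9, Dynlt1b and Ndn among them. Of these 4, only Tmem254 passed on every day and Dynlt1b at days 1 and 30, and Plac9 and Ndn passed at day 1. Chance was argued against for the count of 13. Of 100 relabellings of libraries within days 1, the real one, gave as many, and the highest other gave 2. These relabellings cover the number of genes and not each gene. They do not cover chance differences between animals if the replicates are technical. With labels swapped only within same-numbered pairs at day 7 the highest other gave 0. A library batch seen as carried-over transcripts was argued against at day 30, where Tmem254 and Dynlt1b passed, since each label had 2 libraries with the lung transcript Scgb1a1 and 1 without, a difference of 0. At day 7 the groups differed by 3 libraries, so there the batch and the label cannot be told apart, and a batch that left no such transcripts was not tested. A difference in genetic background or gene copy number between the lines stays open: 4 neighbouring pairs occurred among the 71 genes with p under 0.001, against a median of 2 and a 95th percentile of 4 in random draws. The pairs were Pcsk1 and Glrx, Olig2 and Olig1, Spock3 and Msmo1, and Arxes2 and Arxes1. Plac9, Tmem254 and Duxbl1, which neighbour each other and were all among the 13, had been left out before counting. The count of 4 therefore understates the neighbouring pairs among all genes under that p. An effect of the Alg13 knockout itself was not separated from background, since each genotype label may stand for 1 line.

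The second pattern was the set of 69 genes at day 1. Of 10 splits of the 6 libraries, 2 gave as many genes, the highest other being 84 for wild type replicates 1 and 3 with knockout replicate 3 against the rest, and 10 splits are too few for a share under 0.05. Other-tissue RNA in wild type day 1 replicate 3 was argued against as the whole cause, since 224 genes passed without that library, 58 of the 69 among them. RNA of another brain region in knockout day 1 replicate 3 stays open, since 10 genes passed without that library, 9 of the 69 among them. The 69 genes kept a median of 0.918 of their log2 change there (quartiles 0.835 and 0.983) and 0 fell below 0.5, but they had been picked for differing in all 6 libraries, so this does not decide it. These tests cover the genes and not the lists, and the pan-GABAergic median went from 0.402 to 0.154 without wild type day 1 replicate 3.

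The third pattern was the higher myelin list in libraries labelled knockout at days 7 and 30. A library batch seen as carried-over transcripts was argued against at day 30, where the labels had equal numbers of libraries of each trace group, a difference of 0. At day 7 the difference was 3, so there the batch and the label cannot be told apart. A lower share of neuronal RNA that raises all glial lists alike was argued against at day 30 by the astrocyte median of -0.15 (quartiles -0.221 and -0.12) beside the myelin median of 0.292. The precursor and microglia medians were positive there (0.199 and 0.116), so only a rise of all glial lists together is covered. At day 7 the astrocyte, precursor, microglia and myelin medians were all positive (0.136, 0.052, 0.419 and 0.354), so there this explanation stays open. Animals further along development stay open: on an axis from wild type day 1 to day 30, knockout minus wild type was 0.094 at day 7 (0.549 ± 0.044 against 0.455 ± 0.078, SD, n = 3, exact permutation p = 0.2; same-numbered pairs 0.076, 0.072 and 0.134, exact sign-flip p = 0.25) and -0.03 at day 30 (0.962 ± 0.03 against 0.992 ± 0.014, SD, n = 3, exact permutation p = 0.2). An effect of the knockout on myelination stays open as well and was not tested apart from these.

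For the interaction chance stays open. In relabellings within days 1 of 100, the real one, gave 2 genes or more, and the highest other gave 1. With labels swapped only within same-numbered pairs at day 7, 5 of 100 gave as many, the highest other 20, and with the replicate number as a block the interaction gave 0 genes. For the remaining comparisons 10 splits are too few for a share under 0.05: the real split and the highest other gave 1 and 0 genes at day 7, 3 and 3 at day 30, 6528 and 70 from day 1 to day 7 in wild type, and 6733 and 0 from day 7 to day 30. The number of splits that gave as many genes was 1, 2, 1 and 1 in that order.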

How the results depend on the processing

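The tests with library weights, with a block for the replicate number within each day, without the 3 libraries that hold both Xist and Y-linked transcripts, without both day 7 replicate 3 libraries, within one trace group (libraries with the same carried-over transcripts) and with the trace group as a covariate were chosen after seeing the data. The count test with DESeq2 was not run. Calls on 1 comparison and day rest on 3 libraries per group, and leaving 1 out leaves 2. Absolute depth is unknown, so the number of fragments behind low FPKM values cannot be told, and relative depth differed by up to 1.34 times. At the preset correlation the myelin list was called at days 7 and 30 under 21 of 21 settings and for the mean over days under 33 of 33, and with an estimated correlation only at day 7 (adjusted p of 0.131 at day 30 and 0.0941 for the mean). In fits to more than the 6 libraries compared, Dynlt1b and Tmem254 were called at day 1 under 21 of 21 settings, and with only those 6 they were not. Dynlt1b, Ndn and Tmem254 were called for the mean over days under 33 of 33 settings without a minimum change, and Ndn, at 0.997, was lost at a log2 change of at least 1. Where a value below differs from the one reported, the cause was not tested, except that fewer libraries also lower the power.

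At a pseudocount of 0.1 and of 0.5 the interaction gave 0 and 0 genes. Without a filter the counts were 6 at day 7, 28 at day 30 and 8 for the interaction, and a filter on mean FPKM gave 0 for the interaction. Median-of-ratios scaling gave 40 genes at day 1 and 0 for the interaction. It split the wild type calls into 3156 up and 3118 down from day 1 to day 7 (2787 and 3741 reported), and 3378 and 3252 from day 7 to day 30 (2777 and 3956 reported). Quantile normalization gave 40 higher and 9 lower at day 1 (48 and 21 reported) and 2 and 2 at day 30 (1 and 2 reported). The interaction gave 1 gene without the mean-variance trend and 0 with a robust spread. With the Y-linked covariate there were 1145 genes at day 1 and 48 for the mean over days. A log2 change of at least 1 left 12 at day 1, 3 for the mean, and 1537 (946 up and 591 down) and 1932 (944 up and 988 down) for the 2 wild type steps. Fits of only the 6 libraries compared gave 0 genes at day 1 (limma; 767 at an unadjusted p under 0.05) and 9 at day 7. The pan-GABAergic median at day 1 was 0.402 with an estimated correlation (adjusted p = 0.904).

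With the replicate number as a block, 39 genes were called at day 1, 8 for the mean over days and 0 for the interaction. At day 7, where the numbers were treated as paired, the block changed no call. At days 1 and 30 the numbers were treated as names. The deviations of same-numbered libraries correlated at r of 0.03, 0.13 and 0.10 at day 1 and -0.34, -0.04 and -0.06 at day 30. Of these 6 pairs, 2 of day 1 and 0 of day 30 correlated best with their own number. At day 7, as at day 1, wild type replicates 2 and 3 correlated best with their own number and replicate 1 did not. A replicate block within each day gave 5 genes at day 1, 1 at day 30, 6 for the mean, 0 for the interaction and 4273 from day 7 to day 30 in wild type.

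Library weights gave 138 genes at day 1, 1875 at day 7, 78 for the mean, 17 for the interaction and 10111 from day 7 to day 30 in wild type, and a pan-GABAergic median at day 1 of 0.15 (adjusted p = 0.107). The estimation of the weights stopped before its convergence tolerance was reached. Without the 3 libraries with both sexes' transcripts there were 16 genes at day 1, 2 at day 7 and 0 for the interaction. The pan-GABAergic median at day 1 was then 0.003 (adjusted p = 0.713), and the endothelial median turned to 0.089 (adjusted p = 0.929). Without both day 7 replicate 3 libraries there were 0 genes at day 7, 8 for the mean and 0 for the interaction. Within one trace group day 30 gave 0 genes. The trace group covariate gave 42 at day 1, 0 at day 7, 0 at day 30, 3 for the mean (Tmem254, Dynlt1b and Ndn), 0 for the interaction and 2657 from day 7 to day 30 in wild type. At day 7 the trace groups coincide with the labels, so this fit rests there on the 1 day 1 library of the lung group. In the settings above with 0 genes for the interaction, limma had 767 to 1242 at an unadjusted p under 0.05.

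On leaving out 1 library at a time the counts ranged from 10 to 1531 at day 1, 0 to 2 at day 7, 0 to 16 at day 30, 6 to 57 for the mean and 0 to 4 for the interaction. The pan-GABAergic median at day 1 ranged from 0.154 to 0.717, and the endothelial median from -0.473 to 0.003. At day 7 the precursor median ranged from -0.014 to 0.143 and the choroid plexus median from -0.071 to 0.383.

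Over all settings and lists, the side of the threshold was kept in 547 cases at day 1 and 547 at day 7. It was kept in 539 cases at day 30 and 855 for the mean over days. Direction was checked only for lists and genes called in the reported fit. The kept cases therefore include uncalled ones whose direction may have turned. Calls were lost in 28, 30, 36 and 35 cases and gained in 15, 13, 17 and 26. Of the lists called at days 1 and 7, the direction turned in 2 cases each. For the named genes, the side was kept in 1257, 1134, 1192 and 2098 cases and calls were lost in 115, 7, 24 and 125. Calls were gained in 50, 34, 1 and 17 cases, and 0 of the genes called in the reported fit turned in direction. In wild type, lists kept their side in 566 and 565 cases and genes in 1982 and 2007 for the 2 steps.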

Other observations

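The tests across developmental position here, with their pairs, splits and left-out library, were chosen after the results had been seen.

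Further genes changed with age in wild type beyond those described above. Of 13 perineuronal net genes 4 rose and 6 fell from day 7 to day 30, and the list was not called (median 0.24, adjusted p = 0.774), beside 2777 rises and 3956 falls among all 13347 genes. Hapln4, a link protein of mature nets, rose from 0.161 ± 0.0458 to 29.1 ± 1.47 FPKM (SD, n = 3 each; log2 4.69, adjusted p = 1.4e-09), while tenascin-C, Tnc, and versican, Vcan, fell by 3.27 and 1.90. Of the immediate-early genes, Arc rose at that step from 2.13 ± 1.27 to 32.4 ± 12.9 FPKM (log2 3.41, adjusted p = 3.51e-07) and Egr1 by 2.00. Among GABA receptor subunits Gabrd rose by 2.19 and Gabra5 fell by 1.78, and among NMDA receptor subunits Grin2a rose by 1.81 and Grin2d fell by 1.52.

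Genes of N-glycan assembly, the pathway of Alg13, were also followed with age in wild type. From day 7 to day 30, 8 of 22 genes of lipid-linked oligosaccharide assembly fell and 4 rose, with Alg9 at -1.04 (SE 0.123, adjusted p = 4.29e-06), Alg2 at -0.83 and Dpm1 at 0.89, and 7 of 23 genes of oligosaccharide transfer and glycan processing fell and 0 rose, among them Ddost at -0.67 and Stt3b at -0.56. Neither list was called against the other genes (adjusted p of 0.698 and 0.193), of which 3956 of 13347 fell and 2777 rose.

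The day 7 differences between genotype labels were compared with wild type development. Across genes, which are not independent replicates, the day 7 log2 differences correlated with the wild type change from day 1 to day 30 at r = 0.60 and rho = 0.57, with no libraries in common. This was the largest absolute r of 10 splits of the 6 day 7 libraries (0.602, against 0.054 to 0.598 in the others), and the 3 other splits that swapped labels within same-numbered pairs gave at most 0.461. So few splits cannot give a share under 0.05. Without wild type day 7 replicate 3, at 0.365 on this axis against 0.491 and 0.509 in the other wild type libraries, r was 0.33. That library held the olfactory bulb gene Cdhr1 at 15.5 FPKM, against 1.27 and 1.73 in the other wild type libraries. It also had the highest Dcx of the day 7 libraries, at 147 FPKM. Whether RNA of another brain region set its position was not tested. Dcx differed by -0.50 at day 7 and Mbp by 0.90, both in the direction of older wild type cortex, and neither passed (adjusted p of 1 and 0.384). A hypothesis is that the day 7 animals labelled knockout may have been slightly further along development, but the difference in position of 0.094 had an exact permutation p of 0.2. It had one sign in all 3 same-numbered pairs (0.076, 0.072 and 0.134), too few for an exact sign-flip p under 0.25, so the hypothesis stays open, as does a difference in the hour of birth or dissection.

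Malat1 and Meg3, long non-coding RNAs, were at 24.7 and 79.8 FPKM in knockout day 30 replicate 1 and 26.8 and 98.5 in replicate 3, against 51.6 to 67.3 and 191 to 268 in the other day 30 libraries. These genes were chosen after their values were seen, and no explanation was tested.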
